A study of Oryctolagus cuniculus with 16 samples.

How the data were processed

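Poly(A) RNA of the vagina of female New Zealand White rabbits aged 17 to 19 weeks was sequenced in 16 libraries: 6 control libraries without surgery (control 2, 9, 16, 24, 25 and 29), 3 sham-operated (sham 11, 12 and 14), 3 with an acellular graft (acellular 6, 8 and 10) and 4 with a graft carrying tissue particles, called PLATE (PLATE 1, 5, 9 and 13). Both graft groups were sampled 10 mm from the graft. The labels give no sampling distance for the sham and control libraries, so site cannot be told apart from graft in comparisons with them. Per the labels, the authors prepared stranded libraries, checked reads with FastQC, aligned them with HISAT2 2.2.1 and assigned them to genes with featureCounts; neither the genome build, the annotation nor the strand setting is stated. The deposited table holds raw read counts per gene symbol in whole numbers, for 13001 named genes and 1 line that pools the reads of genes without a symbol. That pooled line took 22.9 to 28.5% of the counts of a library and was left out, so that fold changes and levels (CPM, counts scaled by effective library size) refer to named genes. Columns were matched to samples by the trailing sample index, because the middle number of the description, 101, did not match the column names of the other libraries. The number 9 occurs in a control and in a PLATE label, and the labels do not say whether this is 1 animal. No other number occurs in more than 1 group, and no pairing was modelled, so that control 9 and PLATE 9 are treated as independent.

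Libraries held 20992063 to 30695000 counts, of which 15348880 to 23236339 fell on named genes, and 10797 to 11629 named genes had a count. Of the 13001 genes, 625 had no count in any library and 10942 were tested after filterByExpr. Counts were scaled by the trimmed mean of M values and fitted with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, all 16 libraries in 1 model with a mean per group, which left 12 residual degrees of freedom. The contrasts were the 6 pairs of groups, the equally weighted mean of the 3 operated groups against control, and a joint test among the operated groups. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.44, and the median standard error of a log2 fold change ran from 0.222 (operated against control) to 0.349 (acellular against sham). In counts simulated at this design, the test recovered 64% of genes given a 4-fold change between acellular and control and 28% of those given a 2-fold change. Simulated genes were drawn independently, many were changed at once, and no simulated library stood apart. Recovery in the real libraries can therefore be lower.

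Before the data were examined, 33 gene lists with 1469 entries were written for the cell types of the vaginal wall, matrix, wound repair, immune cells, signalling, metabolism and RNA quality, and 912 entries were among the genes tested. Each list was tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. List p-values of fits with libraries left out use this preset correlation unless an estimated one is named. The preset test treats members as nearly independent. With it, other splits of the same libraries called a median of 13 to 16 lists, depending on the comparison, so small preset p-values are weak evidence. An estimated correlation, fry, which tests whether the genes of a list move on balance in 1 direction, and a two-sided exact permutation test of the mean log2 CPM of the list's members were run beside it. Standard errors (± after a log2 fold change) come from the fit, and levels are given as mean ± SD over libraries.

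The rule for named genes, written before the data were examined, took genes past the threshold whose groups did not overlap and members past the threshold of called lists, and, where none passed, the 5 genes with a symbol and the smallest p, as values. No gene passed in edgeR, so the 5 with the smallest p are named; the up to 3 members with the smallest p of each of the 8 lists with the smallest preset p, and further genes of the closing part, were chosen after their values were seen. A few of the genes chosen are not reported here and were left out of the search for libraries far from their group. A prior count of 2 was used on the log2 scale, and genes with a group at 3 counts or fewer are given as counts.

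Alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 test, limma voom with quality weights, fits of the 2 compared groups alone, covariates for skeletal muscle and for epithelium, and each library left out in turn. Chosen after seeing the data were the removal of control 2 and PLATE 1 together, the epithelium covariate for lists, DESeq2 filtering set for 0.05 and an estimated correlation without those libraries. Depth, share of mitochondrial and unnamed counts and number of genes with a count were compared between each pair of groups by two-sided exact permutation tests (30 tests). The test and its list version were tested on simulated data, and overlap between comparisons that share the controls was set beside simulated unchanged groups and beside controls split into 2 sets of 3.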

Results

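The study asks how the vaginal wall of the rabbit heals around an acellular graft or a graft carrying autologous tissue particles (PLATE), beside sham surgery and no surgery. ESR1, the oestrogen receptor, lay between 161 and 467 CPM in 15 libraries and at 46.8 CPM in PLATE 1. HOXA13, a positional transcription factor, lay between 13.5 and 41.9 CPM in the same 15 libraries and at 6.14 CPM in PLATE 1. The first 2 principal components held 27.1 and 24.2% of the variance. The 4 groups accounted for 20.3% of the variance among libraries against a median of 19.7% for permuted labels (permutation p = 0.445 over 10000 permutations). Along these components 3 libraries lay apart from their groups, control 2, control 9 and PLATE 1. Control 9 scored 65.36 on component 1, the highest of all 16, against -18.05 to -1.62 in the controls other than control 2. Control 2 held almost no columnar epithelium transcripts. CDH1, the epithelial cadherin, was at 1.35 CPM and EPCAM, an epithelial adhesion molecule, at 1.71 CPM, against at least 13.7 and 33.4 CPM in every other library. PLATE 1 was rich in inflammatory and matrix transcripts, with CXCL8, a neutrophil chemokine, at 2380 CPM and MMP1, an interstitial collagenase, at 1960 CPM. In every other library these were at most 258 and 77.2 CPM. Each acellular library held fewer named-gene counts (15.35 to 19.47 M) than each sham library (19.62 to 22.48 M), and a larger mitochondrial share (12.9 to 18.1% against 9.53 to 12.6%). For both measures the two-sided exact permutation p was 0.1, the smallest that 3 against 3 can give and the smallest of 30 such tests of depth and composition (BH-adjusted 0.735). Within groups the Spearman correlation across genes ran from 0.845 to 0.968 in control, 0.979 to 0.986 in sham, 0.937 to 0.974 in acellular and 0.858 to 0.984 in PLATE.

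**Figure D1:**
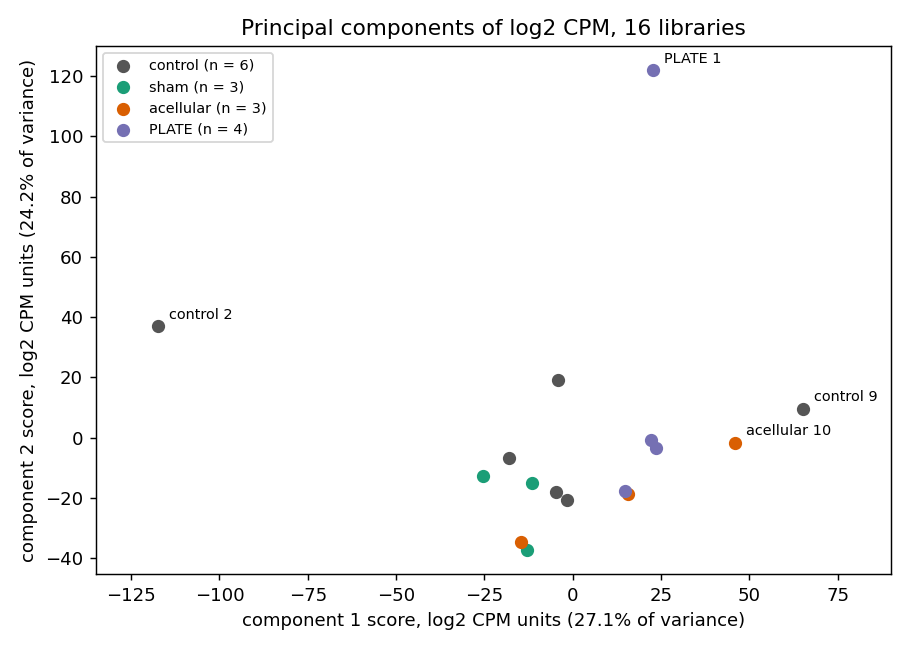
Scores of the 16 libraries on components 1 and 2 of log2 CPM, in log2 CPM units, with 1 point per library and colours for control (n = 6), sham (n = 3), acellular (n = 3) and PLATE (n = 4). Control 2 lies at -117.4 on component 1 and PLATE 1 at 122 on component 2, while the 3 sham libraries lie close together.

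Beside acellular grafts the smooth muscle list, the contractile and cytoskeletal genes of the muscle wall, fell against control: all 32 measured members were lower, with a median log2 fold change of -1.22 (n = 3 against 6; adjusted p = 4.02e-18 with the preset correlation, adjusted p = 0.707 with an estimated correlation). ACTG2, the visceral smooth muscle actin, averaged 1550 ± 270 CPM against 17300 ± 17900 CPM (log2 fold change -3.48 ± 1.01, and -2.81 without control 2). ACTA2, the vascular smooth muscle actin, averaged 2240 ± 447 against 12900 ± 10100 CPM. SMTN, the smooth muscle protein smoothelin, averaged 201 ± 25.6 against 893 ± 687 CPM. Among these 32 genes, 12 passed when adjusted over the list alone (adjusted p = 0.0273 for ACTA2) and 0 over all genes tested. P2RX1, an ATP-gated channel of smooth muscle and platelets, had the smallest p of all genes, with 0.623 ± 0.582 CPM in acellular against 19.9 ± 13 CPM in control. Its log2 fold change was -4.97 ± 0.91 (adjusted p = 0.69), and -6.10 without acellular 10.

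Genes of the fibrillar matrix fell as well beside acellular grafts, 35 of 46 being lower (median -0.52, preset adjusted p = 0.000256, estimated-correlation adjusted p = 0.707). SPARC, a collagen-binding matricellular protein, averaged 431 ± 92.5 against 1080 ± 533 CPM with no overlap of the groups. ADAMTS2, which trims procollagen, averaged 21.5 ± 3.67 against 42.5 ± 16.4 CPM. Interferon-response genes rose, with 34 of 36 higher (median 0.61, preset adjusted p = 7.67e-11, estimated-correlation adjusted p = 0.707). Among them CXCL10, a chemokine for T cells, averaged 91 ± 63.9 against 23.2 ± 15.7 CPM. The interferon median was 0.22 without acellular 10 and 1.04 without control 9. T and NK cell genes rose, 32 of 35 being higher (median 0.68, preset adjusted p = 4.94e-08, estimated-correlation adjusted p = 0.707). IFNG, the type II interferon, averaged 1.15 ± 1.16 against 0.214 ± 0.187 CPM (log2 fold change 2.32, and 1.08 without acellular 8). The T and NK cell median was 1.19 without control 9, 1.05 without acellular 6, 0.42 without acellular 8 and 0.41 without acellular 10. Nuclear genes of oxidative phosphorylation fell by a smaller step, 35 of 38 lower at a median of -0.35 (preset adjusted p = 1.26e-07, estimated-correlation adjusted p = 0.707). Without control 2 the step was -0.21. Columnar epithelium genes rose, 26 of 32 higher (median 0.31, preset adjusted p = 1.98e-06, estimated-correlation adjusted p = 0.713). Without control 2, however, the columnar median was 0.09 with adjusted p = 0.0784. Without acellular 10 it was -0.07, without control 9 it was 0.86, without control 24 it was 0.16 and without acellular 8 it was 0.48.

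In all, 14 of 33 lists changed between acellular and control with the preset correlation (5 up, 9 down), and 0 with an estimated correlation, with fry or by the exact test of list means. By edgeR 0 genes passed, with 656 at an unadjusted p under 0.05 (194 higher, 462 lower) against 547 expected by chance. As many came from 37 of 84 splits of the same libraries into groups of these sizes, the real split included. Voom called 0 genes and DESeq2 10. The DESeq2 calls included P2RX1 (adjusted p = 3.27e-08), ACTG2 (0.0137) and ACTA2 (0.0338), all lower. Also among the 9 lower genes were IL17B, an interleukin 17 family cytokine, at 1.37 ± 0.287 against 14.1 ± 9.95 CPM, and TINAGL1, a basement membrane-associated protein, at 25.1 ± 4.83 against 86.5 ± 39 CPM. The 1 higher gene was IRS4, an insulin receptor substrate with 143 counts in acellular 6 and 15 and 3 in the other acellular libraries. With the low-count filtering of DESeq2 set for 0.05, chosen after seeing the data, 3 of these 10 were called again, ACTA2, ACTG2 and PCP4, a calmodulin-binding protein. The other 7, P2RX1, IL17B, TINAGL1 and IRS4 among them, were filtered out without an adjusted p, and 14 other genes were called. PTPN11, the phosphatase SHP2, was among the 5 genes with the smallest p in edgeR (log2 fold change -0.75 ± 0.185, adjusted p = 0.827). Groups did not overlap for 189 genes, 1.73% of those tested where chance gives 2.38%.

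**Figure D2:**
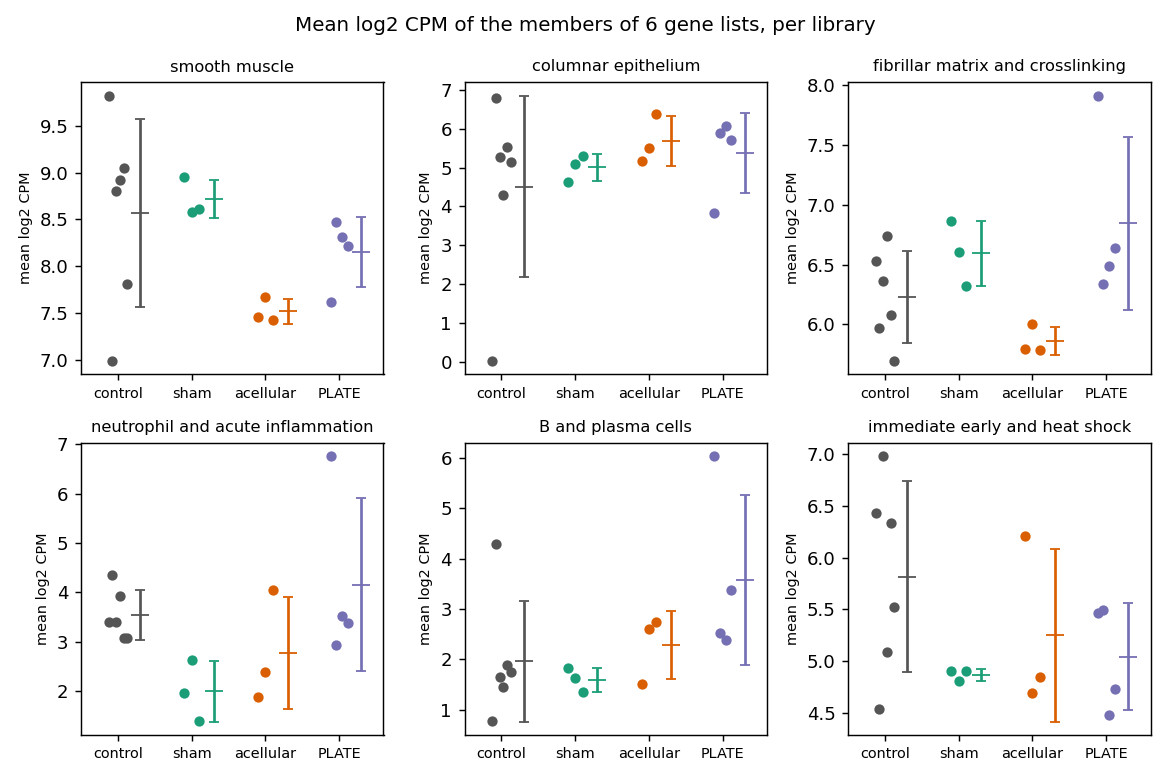
Mean log2 CPM of the measured members of 6 gene lists, with 1 point per library and bars for mean ± SD of control (n = 6), sham (n = 3), acellular (n = 3) and PLATE (n = 4). Smooth muscle values of the 3 acellular libraries run from 7.42 to 7.68, below all sham libraries (8.58 to 8.95), while control libraries spread from 6.99 to 9.82.

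Set against sham, the acellular libraries were lower in genes of muscle, fibroblasts, matrix and nerve. Smooth muscle genes fell, 31 of 32 lower at a median of -1.15 (n = 3 against 3; preset adjusted p = 1.24e-18, estimated-correlation adjusted p = 0.345), with SMTN at 201 ± 25.6 against 795 ± 170 CPM. Fibroblast genes fell, 25 of 29 lower at a median of -0.81 (preset adjusted p = 4.91e-09, estimated-correlation adjusted p = 0.171). THY1, a surface glycoprotein of fibroblasts, averaged 119 ± 7.36 against 345 ± 143 CPM, a log2 fold change of -1.54 ± 0.315. It was the only member to pass when adjusted over the list alone (adjusted p = 0.00556, against 0.902 over all genes). Fibrillar matrix genes fell, 42 of 46 lower at a median of -0.77 (preset adjusted p = 3.21e-11, estimated-correlation adjusted p = 0.345). ADAMTS2 had a log2 fold change of -1.39 ± 0.435 and EMILIN1, an elastic fibre glycoprotein, -1.33 ± 0.478. Schwann cell and nerve genes fell, 20 of 24 lower at a median of -1.06 (preset adjusted p = 1.18e-06, estimated-correlation adjusted p = 0.298). SOX10, the transcription factor of Schwann cells, averaged 2.1 ± 0.805 against 5.28 ± 1.6 CPM and L1CAM, a neural adhesion molecule, 4.81 ± 1.07 against 17.4 ± 4.19 CPM.

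Immune and columnar epithelium lists went the other way between acellular and sham. Columnar epithelium genes rose, 31 of 32 higher at a median of 0.71 (preset adjusted p = 0.000233, estimated-correlation adjusted p = 0.623), and at 0.36 with adjusted p = 0.0487 without acellular 10. Interferon-response genes rose (34 of 36 higher, median 0.80, preset adjusted p = 1.43e-07, estimated-correlation adjusted p = 0.547), as did genes of antigen presentation by MHC class II (14 of 16 higher, median 1.29, preset adjusted p = 2.89e-05, estimated-correlation adjusted p = 0.547). HLA-DRA, the alpha chain of the class II molecule DR, averaged 1130 ± 737 against 321 ± 38.5 CPM. T and NK cell genes rose too (33 of 35 higher, median 1.00, preset adjusted p = 1.25e-06, estimated-correlation adjusted p = 0.547). Without acellular 10 the interferon median was 0.36, and without acellular 8 the T and NK cell median was 0.64. Acellular 6 did not share these rises. Its class II list mean of 3.02 log2 CPM lay below every sham library (3.19 to 3.37). The same held for its T and NK cell mean of 0.54 (0.81 to 0.93 in sham). Its interferon mean of 5.12 lay inside the sham range (4.73 to 5.66). MCAM, an adhesion molecule of smooth muscle and endothelium, had a log2 fold change of -1.71 ± 0.443 and GPAT3, an enzyme of triglyceride synthesis, -1.13 ± 0.26. WNT2B, a Wnt ligand, stood at -1.20 ± 0.287 and PLXNB3, a semaphorin receptor, at -1.44 ± 0.368. Adjusted p was 0.902 for each of these. With the preset correlation 18 lists changed (10 up, 8 down), and 0 with an estimated correlation or fry. EdgeR called 0 genes, with 533 at an unadjusted p under 0.05 (193 higher, 340 lower) against 547 expected. DESeq2 called 1 (THY1, adjusted p = 0.0275) and voom 72 (31 higher, 41 lower, THY1 among them). All 72 voom calls lay just under the threshold, at adjusted p of 0.0495 to 0.0498 (THY1 0.0495). The smallest p an exact test can give for 3 against 3 is 0.1. Groups did not overlap for 2006 genes, 18.3% where chance gives 10%, but the spread of that share under chance was not computed.

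Between the graft types, genes of the fibrillar matrix and its crosslinking rose in PLATE against acellular: 43 of 46 members were higher, with a median log2 fold change of 1.06 (n = 4 against 3; preset adjusted p = 3.56e-20, estimated-correlation adjusted p = 0.428). Acellular list means were low, at 5.79 to 6.00 log2 CPM against 6.32 to 6.86 in sham and 5.70 to 6.74 in control. PLATE 5, PLATE 9 and PLATE 13, at 6.34 to 6.64, lay inside the sham and control ranges, and PLATE 1 was at 7.91. SPARC averaged 1180 ± 296 against 431 ± 92.5 CPM (log2 fold change 1.46 ± 0.443) and ADAMTS2 70.1 ± 35.1 against 21.5 ± 3.67 CPM (1.71 ± 0.421). BMP1, the procollagen C-proteinase, averaged 142 ± 154 against 38.6 ± 2.66 CPM (1.88 ± 0.563). Over the list alone 15 of the 46 passed, SPARC, ADAMTS2 and BMP1 among them (adjusted p = 0.0463 each), and 0 over all genes tested. Without PLATE 1 the list's median was 0.58 with preset adjusted p = 1.48e-16, SPARC stood at 1.28, ADAMTS2 at 1.36 and BMP1 at 0.75. With an estimated correlation and without control 2 and PLATE 1, 0 of the 18 lists called for these 2 groups passed.

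Smooth muscle genes rose in PLATE against acellular too, all 32 members being higher at a median of 0.72 (preset adjusted p = 1.96e-06, estimated-correlation adjusted p = 0.52). Without PLATE 1 the median was 0.71. Here too the contrast reflects low acellular values (list means 7.42 to 7.68 log2 CPM). The PLATE means, 7.62 to 8.48, lay below every sham library (8.58 to 8.95) and inside the control range (6.99 to 9.82). ACTG2 averaged 8190 ± 4770 against 1550 ± 270 CPM and ACTA2 7230 ± 1980 against 2240 ± 447 CPM, with no overlap of the groups for either gene. P2RX1 again had the smallest p of all genes, at 10.1 ± 4.92 against 0.623 ± 0.582 CPM. Its log2 fold change was 4.00 ± 0.891 (adjusted p = 0.875), and 5.13 without acellular 10. FNDC1, a secreted fibronectin-domain protein, averaged 94.3 ± 40.9 against 31.7 ± 10.8 CPM, and PPP1R1B, a phosphatase inhibitor, 0.593 ± 0.165 against 2.89 ± 0.658 CPM. NOX4, an NADPH oxidase that makes hydrogen peroxide, had 11 to 89 counts in each PLATE library and 3 counts over the 3 acellular libraries together. Cell cycle genes rose (42 of 43 higher, median 1.59, preset adjusted p = 9.67e-11, estimated-correlation adjusted p = 0.52). That median was 0.42 without PLATE 1. B and plasma cell genes rose by a median of 2.35 (24 of 25 higher, preset adjusted p = 1.76e-06, estimated-correlation adjusted p = 0.52). Once PLATE 1 was left out, the median was 0.36 with adjusted p = 0.0685. Interferon-response genes fell, 31 of 36 lower at a median of -0.54 (preset adjusted p = 0.000271, estimated-correlation adjusted p = 0.615). This was -0.84 without acellular 6 and -0.09 with adjusted p = 0.665 without acellular 10.

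With the preset correlation 18 lists changed between PLATE and acellular (15 up, 3 down), and 0 with an estimated correlation, with fry or by the exact test of list means, whose smallest possible p is 0.0286. By edgeR 0 genes passed, with 515 at an unadjusted p under 0.05 (395 higher, 120 lower) against 547 expected. Voom called 0 genes and DESeq2 1, P2RX1 (adjusted p = 0.00175). Groups did not overlap for 545 genes, 4.98% where chance gives 5.71%.

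**Figure D3:**
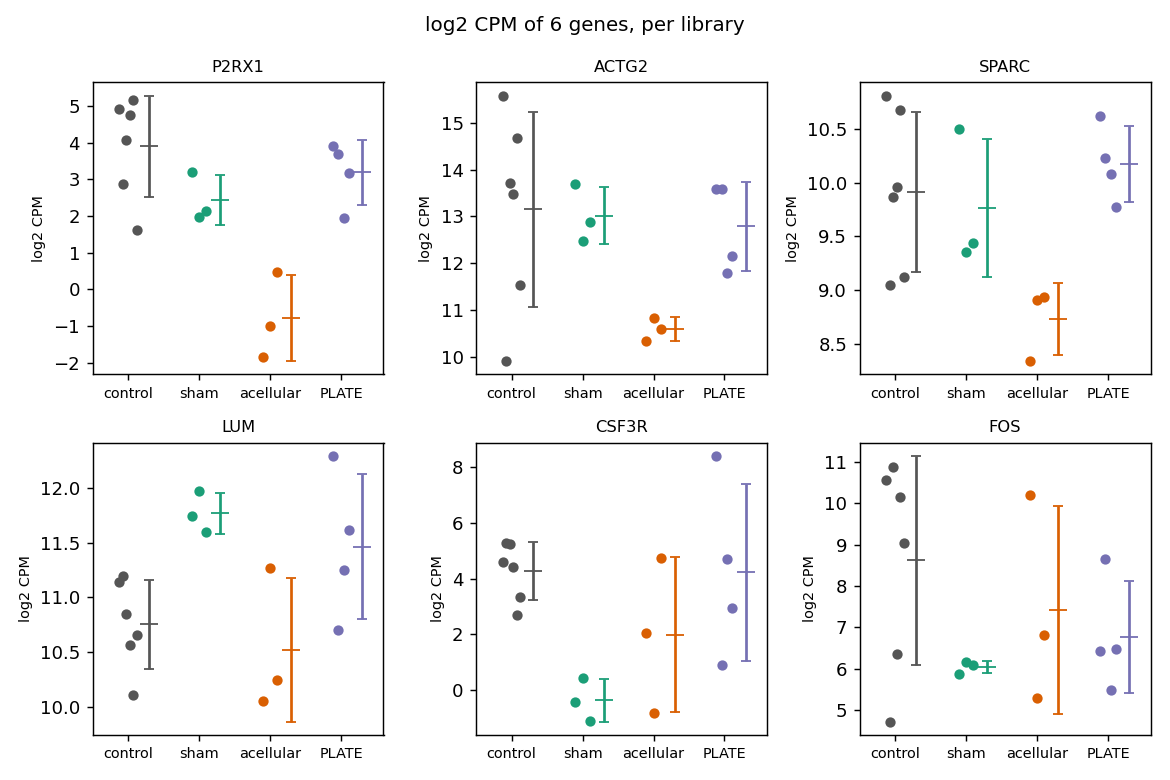
log2 CPM of 6 genes, with 1 point per library and bars for mean ± SD of control (n = 6), sham (n = 3), acellular (n = 3) and PLATE (n = 4). P2RX1 lies at or below 1.28 CPM in the acellular libraries and at 3 CPM or more in all other libraries, and LUM is higher in each sham library than in each control library.

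Against control, PLATE libraries were higher in genes of lymphocytes and antigen presentation. T and NK cell genes rose, 33 of 35 being higher (median 1.31, n = 4 against 6, preset adjusted p = 1.45e-19, estimated-correlation adjusted p = 0.298). B and plasma cell genes rose, all 25 being higher (median 1.95, preset adjusted p = 9.98e-19, estimated-correlation adjusted p = 0.298). Genes of antigen presentation by MHC class II rose, all 16 being higher (median 1.57, preset adjusted p = 8.83e-17, estimated-correlation adjusted p = 0.298). Without PLATE 1 these medians were 0.61, 0.32 and 0.70, each still past the threshold with the preset correlation. HLA-DMA, which loads peptides on class II molecules, averaged 97 ± 95.7 against 28.9 ± 23.9 CPM (log2 fold change 1.74 ± 0.58, and 0.77 without PLATE 1). IGHM, the immunoglobulin mu chain, averaged 9430 ± 14600 against 1220 ± 1690 CPM. Its log2 fold change was 2.95 ± 0.963, with 0.82 without PLATE 1 and 4.11 without control 9. Of the 16 class II genes, 11 passed when adjusted over the list alone and 0 over all genes tested. CD28, the T cell costimulatory receptor, averaged 2.26 ± 1.15 against 0.574 ± 0.632 CPM (log2 fold change 1.93 ± 0.655, and 2.76 without control 9).

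Fibrillar matrix genes rose in PLATE against control (41 of 46 higher, median 0.47, preset adjusted p = 6.32e-13, estimated-correlation adjusted p = 0.298). Without PLATE 1 the matrix median was 0.08. When adjusted over the list alone 4 members passed, among them P4HA3, a collagen prolyl hydroxylase, at 20.4 ± 25.1 against 4.01 ± 2.84 CPM (log2 fold change 2.34 ± 0.648, and 0.97 without PLATE 1). Macrophage genes rose by a median of 1.08 (31 of 37 higher, preset adjusted p = 6.42e-12, estimated-correlation adjusted p = 0.392). Without PLATE 1 the macrophage median was 0.08 with adjusted p = 0.237. Immediate early and heat shock genes fell, 29 of 32 lower at a median of -0.77 (preset adjusted p = 2e-10, estimated-correlation adjusted p = 0.298) and at -1.15 without PLATE 1. NR4A1, an immediate early nuclear receptor, averaged 12.6 against 84.6 CPM (log2 fold change -2.74 ± 1.13, and -1.70 without control 16). The list means of control 9 and control 24, 4.535 and 5.088 log2 CPM, lay inside the PLATE range (4.484 to 5.493). Smooth muscle genes fell, all 32 lower at a median of -0.66 (preset adjusted p = 2.24e-07, estimated-correlation adjusted p = 0.466). Without control 2 the muscle median was -0.32, and without control 2 and PLATE 1 together -0.17 with adjusted p = 0.813.

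Of the 5 genes with the smallest p between PLATE and control (adjusted p = 0.998 each), FNDC1 kept its size without PLATE 1 (log2 fold change 1.29 ± 0.296, and 1.05 without it). C1QTNF3, a secreted protein of the C1q family, stood at 2.43 ± 0.652 (1.75 without PLATE 1). COL8A2, a collagen VIII chain, stood at 3.49 ± 0.865 (0.71 without PLATE 1) and BST1, an ADP-ribosyl cyclase, at 2.51 ± 0.632 (0.74 without PLATE 1). IBSP, the bone sialoprotein, was at 226 CPM in PLATE 1 and at most 0.148 CPM in the other PLATE libraries, against up to 1.68 CPM in control. In all 21 lists changed with the preset correlation (15 up, 6 down, and 13 in all without PLATE 1) and 0 with an estimated correlation, with fry or by the exact test of list means. By edgeR 0 genes passed, with 480 at an unadjusted p under 0.05 (361 higher, 119 lower) against 547 expected, and DESeq2 and voom each called 0. Groups did not overlap for 13 genes, 0.119% where chance gives 0.952%.

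Set against sham, PLATE libraries were higher in genes of antigen presentation, B cells and neutrophils. Genes of antigen presentation by MHC class II rose, all 16 higher at a median of 2.31 (n = 4 against 3; preset adjusted p = 5.72e-13, estimated-correlation adjusted p = 0.305). When adjusted over the list alone 13 of them passed, and without PLATE 1 the median was 1.57. B and plasma cell genes rose, all 25 higher at a median of 3.00 (preset adjusted p = 5.72e-13, estimated-correlation adjusted p = 0.364). Of these 18 passed when adjusted over the list alone, and the median was 1.35 without PLATE 1. Neutrophil and acute inflammation genes rose, 24 of 25 higher at a median of 2.68 (preset adjusted p = 1.24e-09, estimated-correlation adjusted p = 0.305). Here 11 passed when adjusted over the list alone, and the median was 1.17 without PLATE 1. This contrast also reflects low sham values: list means ran from 1.403 to 2.633 log2 CPM in sham and 3.075 to 4.353 in control. Against control the neutrophil median of PLATE was 1.16, and -0.77 without PLATE 1 (preset adjusted p = 0.068). CSF3R, the receptor of granulocyte colony-stimulating factor, averaged 91.7 ± 160 against 0.756 ± 0.446 CPM (log2 fold change 6.92 ± 1.82, and 3.95 without PLATE 1). It was at 332 CPM in PLATE 1 and at most 38.1 CPM in every other library, and control averaged 22.9 ± 13.4 CPM. CCR7, a homing receptor of lymphocytes and dendritic cells, averaged 10.2 ± 12.8 against 0.921 ± 0.301 CPM (log2 fold change 3.46, and 2.04 without PLATE 1). IDO1, a tryptophan-degrading enzyme, averaged 294 ± 525 against 5.03 ± 2.34 CPM (5.87 ± 1.47, and 2.65 without PLATE 1).

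Schwann cell and nerve genes fell in PLATE against sham, 19 of 24 lower at a median of -0.74 (preset adjusted p = 1.99e-06, estimated-correlation adjusted p = 0.305) and -0.79 without PLATE 1. SOX10 averaged 2.08 ± 0.706 against 5.28 ± 1.6 CPM, with no overlap of the groups. TCN1, a vitamin B12-binding protein, had 15 to 798 counts per PLATE library and 5 counts over the 3 sham libraries. GPAT3 had a log2 fold change of -0.95 ± 0.239 and PLEKHB1, a pleckstrin homology domain protein, -1.44 ± 0.356 (adjusted p = 0.657 each). With the preset correlation 18 lists changed (12 up, 6 down), and 0 with an estimated correlation, with fry or by the exact test of list means. By edgeR 0 genes passed, with 821 at an unadjusted p under 0.05 (640 higher, 181 lower) against 547 expected. As many came from 5 of 35 splits of the same libraries into groups of these sizes, the real split included (median of the others 382.5). Voom called 0 genes and DESeq2 14, of which 13 were higher in PLATE, CSF3R (adjusted p = 0.00232) and CCR7 (0.00772) among them. Groups did not overlap for 1625 genes, 14.9% where chance gives 5.71%, but the spread of that share under chance was not computed.

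Sham surgery alone went with more fibroblast and fewer neutrophil transcripts than control. Fibroblast genes rose, 22 of 29 higher at a median of 0.42 (n = 3 against 6; preset adjusted p = 2.57e-11, estimated-correlation adjusted p = 0.0661). Each sham library had a higher list mean than each control library (8.26 against 7.70 log2 CPM, two-sided exact permutation p = 0.0119, the smallest possible, BH-adjusted 0.196). LUM, the collagen-binding proteoglycan lumican, averaged 3510 ± 461 against 1780 ± 470 CPM and OGN, the proteoglycan osteoglycin, 2120 ± 386 against 941 ± 364 CPM. DPT, the matrix protein dermatopontin, averaged 469 ± 54.9 against 211 ± 125 CPM, and the groups overlapped for none of these 3. Neutrophil and acute inflammation genes fell, 23 of 25 lower at a median of -1.83 (preset adjusted p = 1.04e-09, estimated-correlation adjusted p = 0.293). Each sham library lay below each control library (list means 2.00 against 3.54 log2 CPM, exact permutation p = 0.0119, BH-adjusted 0.196). CSF3R averaged 0.756 ± 0.446 against 22.9 ± 13.4 CPM and CXCR1, a chemokine receptor of neutrophils, 1.93 ± 1.01 against 22 ± 12.6 CPM.

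Immediate early and heat shock genes fell in sham against control, 31 of 32 lower at a median of -0.87 (preset adjusted p = 9.08e-11, estimated-correlation adjusted p = 0.293). EGR3, an immediate early transcription factor, had a log2 fold change of -3.42 ± 0.998 and -2.36 without control 16. The list mean of control 9, 4.535 log2 CPM, lay below every sham library (4.805 to 4.904). Mitochondrial genome transcripts fell by a median of 0.77 on the log2 scale, all 13 lower (preset adjusted p = 2.82e-05, estimated-correlation adjusted p = 0.66). The median was -0.20 without control 2, in which these transcripts took 26.0% of counts against 8.92 to 18.1% in the other libraries. TENM2, a teneurin adhesion protein, averaged 2.18 ± 1.24 against 0.215 ± 0.18 CPM and VIT, the matrix protein vitrin, 18.2 ± 7.97 against 4.68 ± 2.35 CPM. PRSS12, a secreted serine protease, averaged 33.9 ± 11.3 against 12.6 ± 4.6 CPM. SGK1, a glucocorticoid-induced kinase, averaged 33.3 ± 11.4 against 72.7 ± 18.7 CPM and CHST2, a sulfotransferase, 17.8 ± 0.599 against 31.5 ± 7.61 CPM. Adjusted p was 0.963 for these 5 genes, those with the smallest p. With the preset correlation 20 lists changed (7 up, 13 down, and 13 in all without sham 14), and 0 with an estimated correlation, with fry or by the exact test of list means. By edgeR 0 genes passed, with 326 at an unadjusted p under 0.05 (133 higher, 193 lower) against 547 expected, and DESeq2 and voom each called 0. Groups did not overlap for 404 genes, 3.69% where chance gives 2.38%.

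**Figure D4:**
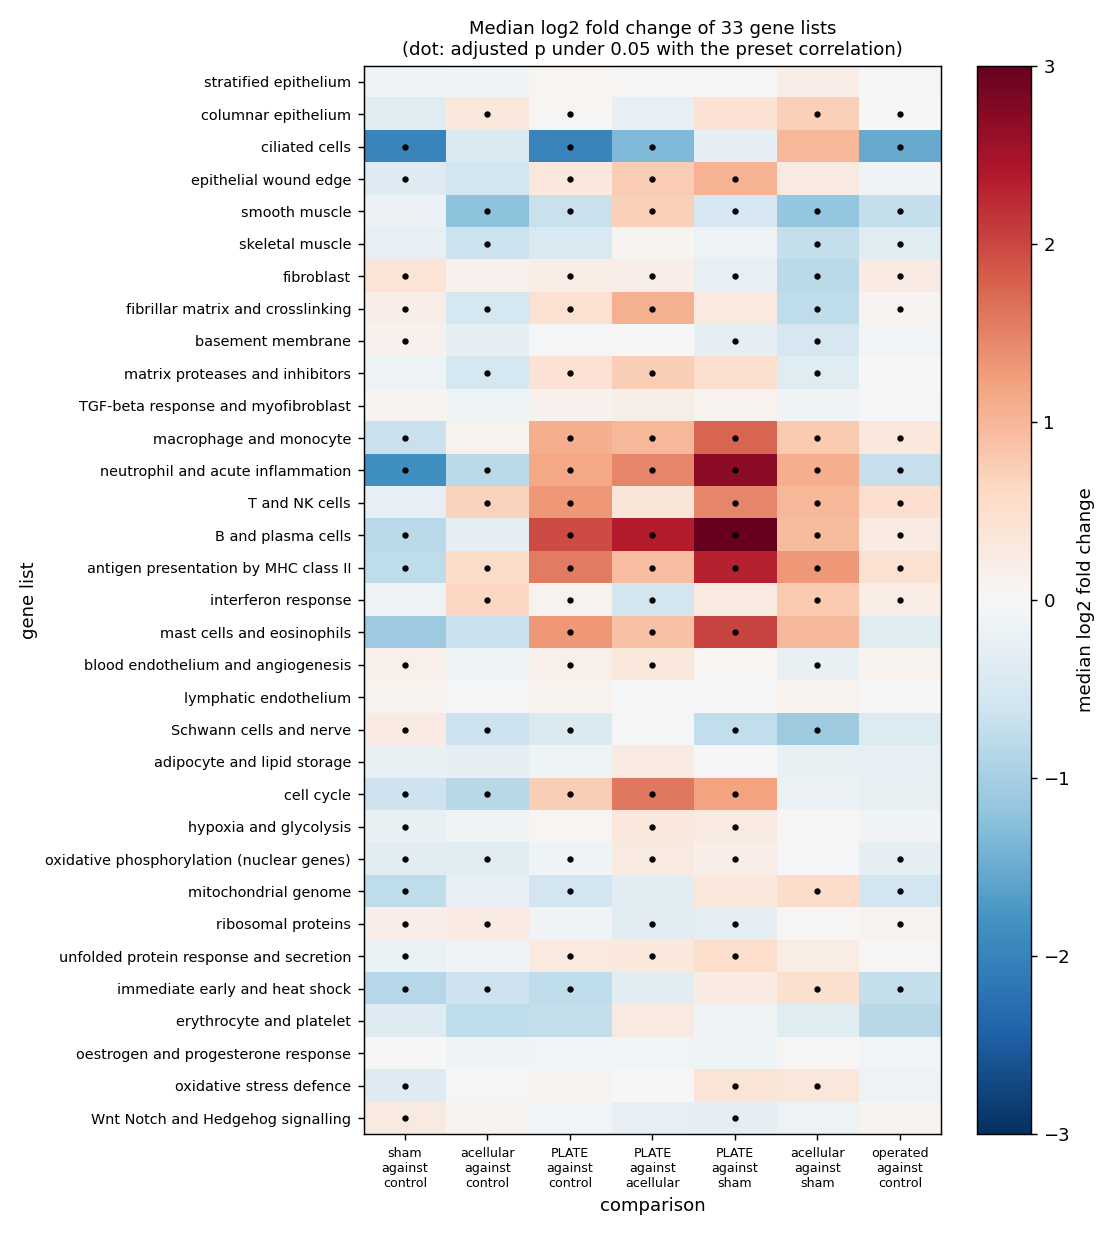
Median log2 fold change (colour) of the 33 gene lists (vertical axis) in the 7 comparisons (horizontal axis), with a dot where the list passed with the preset correlation. The smooth muscle median is -1.22 for acellular against control, -1.15 for acellular against sham and 0.72 for PLATE against acellular.

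Taking the 3 operated groups together against control, immediate early and heat shock genes fell. All 32 were lower, at a median of -0.70 (n = 10 against 6; preset adjusted p = 3.06e-16, estimated-correlation adjusted p = 0.377). Of these 7 passed when adjusted over the list alone. FOSB, a subunit of the AP-1 transcription factor, averaged 18.9 ± 25.4 against 162 ± 194 CPM (log2 fold change -3.44 ± 0.985, -2.68 without control 16 and -4.06 without PLATE 5). The controls were not uniform. FOSB was at 2.68 CPM in control 9 and 2 CPM in control 24, below every operated library (3.2 CPM or more). The list means of these 2 controls, 4.535 and 5.088 log2 CPM, lay inside the range of the operated libraries (4.484 to 6.205). DUSP2, a phosphatase of MAP kinases, averaged 0.846 ± 0.607 against 3.29 ± 2.66 CPM. Smooth muscle genes fell, 31 of 32 lower at a median of -0.71 (preset adjusted p = 1.29e-11, estimated-correlation adjusted p = 0.697) and at -0.30 without control 2. Without control 2 and PLATE 1 together the muscle median was -0.30 with adjusted p = 0.0935. T and NK cell genes rose, 29 of 35 higher at a median of 0.51 (preset adjusted p = 1.26e-10, estimated-correlation adjusted p = 0.697). IFNG averaged 1.17 ± 0.921 against 0.214 ± 0.187 CPM. The T and NK cell median was 0.31 without control 2, 0.95 without control 9 and 0.17 with adjusted p = 0.0246 without control 2 and PLATE 1. P2RX1 averaged 5.96 ± 5.23 against 19.9 ± 13 CPM and IL17B 5.02 ± 3.03 against 14.1 ± 9.95 CPM. PRKAG2, a subunit of the energy-sensing kinase AMPK, averaged 75.1 ± 12.3 against 117 ± 35.7 CPM, and NOL3, an inhibitor of apoptosis, 1.14 ± 0.536 against 2.58 ± 1.25 CPM. With the preset correlation 16 lists changed (9 up, 7 down), and 0 with an estimated correlation, with fry or by the permutation test of list means. By edgeR 0 genes passed, with 425 at an unadjusted p under 0.05 (96 higher, 329 lower) against 547 expected. Voom called 0 genes and DESeq2 1, P2RX1 (adjusted p = 0.00256).

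Among the 3 operated groups tested jointly, edgeR called 0 genes, with 621 at an unadjusted p under 0.05 against 547 expected and a smallest adjusted p of 0.801. DESeq2 and voom each called 0. No gene was called in any pair of comparisons against control (0 shared, 0 expected). Across genes, which are not independent replicates, the log2 fold changes of sham and acellular against the same controls had a Pearson r of 0.355 and a covariance of 0.102, above the highest of 20 simulated unchanged pairs that share those controls (0.0866). With controls split into sets of 3 the mean covariance was -0.0366, with a range of -0.174 to 0.0434 over 20 splits. Simulated genes were drawn independently, so the simulations can understate the spread, and a change shared by sham and acellular is not shown. For sham and PLATE the covariance was 0.0291 and for acellular and PLATE 0.075, both under the simulated means of 0.0793 and 0.0784.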

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

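In this part, the tests on control 2 and PLATE 1 and the search for libraries far from their group were chosen only after the result was seen; those on the smooth muscle list were set before its adjusted medians were known, but the p they are read against was chosen after.

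Control 2 stands far from the other controls in 4 measures: 10797 genes with a count (11427 to 11629 in the others), a scaling factor of 0.592 (0.950 to 1.155), a columnar epithelium mean of 0.018 log2 CPM (4.31 to 6.80) and CDH1 at 0.54 log2 CPM (5.18 to 7.34). A shallow library is argued against by its 18.78 M named-gene counts before scaling, inside the range of the others (15.35 to 23.24 M). The low scaling factor makes its effective library size smaller than that total, and effective sizes were not compared. A fault of scaling is argued against by the difference between the columnar epithelium and fibroblast lists within the library, which no scaling moves: -7.76 on the log2 scale, against -3.82 to -1.02 elsewhere. A candidate explanation is a sample of muscle wall with little mucosa: of the 32 columnar epithelium members 31 are lowest, and of the 32 smooth muscle members 26 highest, in control 2, with HOXA13 at 41.9 CPM and ESR1 at 264 CPM still expressed. The smooth muscle count depends on the scaling, since the low factor raises all CPM of control 2. Its smooth muscle mean was 9.82 log2 CPM against 9.05 in control 25, the next highest, and no scaling-free difference was computed for this list. The labels name no layer of the wall, so a difference in sampling stays a hypothesis, and no biological explanation beyond it was tested. RNA quality was not tested as an explanation either. Mitochondrial transcripts took 26.0% of the named-gene counts of control 2, against 8.92 to 18.1% elsewhere. The mitochondrial genome, ribosomal protein and oxidative phosphorylation lists were highest in it.

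PLATE 1 stands far from the other PLATE libraries in 13 measures. Among list means, in log2 CPM, it had columnar epithelium at 3.83 (5.72 to 6.07 in the others), neutrophil and acute inflammation at 6.76 (2.94 to 3.53), hypoxia and glycolysis at 6.60 (5.70 to 5.82), unfolded protein response at 7.64 (6.64 to 6.79) and Wnt, Notch and Hedgehog signalling at 2.52 (3.38 to 3.55). Among genes, in log2 CPM, it had IBSP at 7.82, P4HA3 at 5.86, FBN2 at 5.02, IL1A at 7.29, IL1B at 10.89, IFIT2 at 2.67, IRF4 at 5.77 and MANF at 8.15. A fault of scaling is argued against by the difference between the neutrophil and fibroblast lists within the library, -0.811 on the log2 scale against -6.80 to -3.44 elsewhere. A response shared by the PLATE group, stronger in PLATE 1, stays open. In the neutrophil list, where PLATE 1 was seen to stand apart, 0 of the other 3 PLATE libraries lie above the highest control (4.35), but all 3 lie above the highest sham library (2.63). The bound for this test was widened to sham after these values were seen. That the sample may hold wound or granulation tissue stays open too: 13 of 33 lists are highest in PLATE 1, against at most 5 in any other library, but no label describes the sample, and a wound in that animal and tissue taken nearer to a wound cannot be told apart.

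The smooth muscle list was lower in acellular than in control libraries, at a median log2 fold change of -1.22. More epithelium in the acellular samples could lower it: with the mean of the epithelium lists as a covariate the median was -0.677 (preset adjusted p = 2.63e-12, estimated-correlation adjusted p = 0.745). Control 2, rich in muscle, could raise the controls: without it the median was -0.844 (preset adjusted p = 1.04e-13, estimated-correlation adjusted p = 0.819). Both medians met the bound set against these explanations when read with the preset p, but the bound named no correlation, and the preset p takes no account of members that move together across libraries (estimated correlation 0.607). Read with the estimated correlation, a choice made after the values were seen, neither explanation is excluded. That reading could hardly exclude them, since the list had an estimated-correlation adjusted p of 0.707 in the main fit already. The 2 explanations thus cannot be told apart from an effect of the graft. The graft remains among the open explanations, with all 3 acellular libraries at 7.42 to 7.68 log2 CPM and all 3 sham libraries at 8.58 to 8.95. Control 2 takes no part in that difference from sham. The sampling site of sham and control libraries is not given, so a difference of site cannot be told apart from the graft either.

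Other libraries lay far from their group in single values, in log2 CPM. Control 9 had the B and plasma cell list at 4.29 (0.77 to 1.88 in the other controls), CD40LG at 1.496 (-0.45 to 0.22) and HLA-DMA at 6.27 (3.72 to 4.62). Control 24 had the adipocyte list at 4.77 (4.16 to 4.39), control 16 had SGK1 at 6.77 (5.91 to 6.23), and control 25 had COL8A2 at 0.37 (-0.82 to -0.45). PLATE 5 had ribosomal proteins at 9.83 (10.24 to 10.32 in the other PLATE libraries) and EGR1 at 7.95 (4.71 to 5.19). In all, 25 of 231 values examined had a gap to the nearest library past Dixon's 95% limit for the group, where chance alone gives about 11.6; groups of 3 were not examined, and many of the genes examined were chosen for differences that PLATE 1 itself widens.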

How the results depend on the processing

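Of the alternatives here, leaving out control 2 and PLATE 1 together, with or without an estimated correlation, the epithelium covariate for lists and DESeq2 filtering set for 0.05 were chosen only after the result was seen. Of 143 counts of genes under alternatives, 132 stayed at 0, including all that left out 1 library (0 to 0 in each comparison). The other 11 came from other tools. DESeq2 gave 10 for acellular against control, 1 for PLATE against acellular, 14 for PLATE against sham, 1 for acellular against sham and 1 for operated against control. Its filtering set for 0.05 gave 17, 1, 14, 1 and 1 for the same comparisons. For acellular against control only 3 of the 10 and the 17 genes were shared, because the other 7 were filtered out and got no adjusted p, and in the other 4 comparisons the genes were the same. Voom with quality weights gave 72 for acellular against sham, all at adjusted p of 0.0495 to 0.0498. The cause of the differences between tools was not tested. Counts of lists changed, above 0 in all 7 comparisons with the preset correlation, were 0 in each with an estimated correlation (from 20 for sham against control, 14 for acellular against control, 21 for PLATE against control, 18 each for PLATE against acellular, PLATE against sham and acellular against sham, and 16 for operated against control). They were again 0 in each with an estimated correlation without control 2 and PLATE 1. The estimated test allows for members that move together. With the preset correlation, leaving out control 2 and PLATE 1 gave 12 lists for PLATE against control and 9 for operated against control. Of the 21 lists changed for PLATE against control, 11 kept direction and side of the threshold there, 9 no longer passed and 1 turned. That 1 was the cell cycle list, whose median went from 0.735 to -0.613 (adjusted p = 0.000313), and was -0.432 with adjusted p = 0.153 without PLATE 1 alone. Leaving out 1 library gave 13 to 22 for sham against control (13 without sham 14), 11 to 15 for acellular against control, 13 to 22 for PLATE against control (13 without PLATE 1), 12 to 22 for PLATE against acellular, 17 to 21 for PLATE against sham, 17 to 23 for acellular against sham and 11 to 18 for operated against control. Of 3494 alternative log2 fold changes of named genes, 3450 kept direction and side of the threshold, 37 passed it (15 with DESeq2, 12 with its filtering set for 0.05, 10 with voom) and 7 reversed, all for PLATE against control: IBSP to -1.48 with voom, and, without PLATE 1 and without control 2 and PLATE 1, COL11A1 to -0.24 and -0.39, MYBL2 to -0.51 and -0.77, and AURKA to -0.31 and -0.52, where PLATE 1 held the highest value. Leaving out 1 library gave -0.24 to 5.71 for COL11A1, -0.51 to 2.69 for MYBL2 and -0.31 to 1.64 for AURKA. Overlap between comparisons against control was 0 genes with shared and with split controls, which shows no stability, since each comparison called 0 genes with shared controls. No paired analysis was possible because only the number 9 occurs in more than 1 group. Without control 9, PLATE against control kept its 21 lists. Depth sets a floor for low genes, since 3 counts correspond to 0.129 to 0.195 CPM before the scaling factors are applied. With scaling the floor is higher in control 2, where 2 counts of TP63 gave 0.18 CPM. In counts simulated at the depth, group sizes and gene-wise spread of these libraries, 28% of 2-fold and 94% of 16-fold changes between acellular and control were recovered, and depth was not varied. The simulated genes were independent and no simulated library stood apart, so these shares can overstate recovery here. A count of 0 genes therefore does not exclude large changes.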

Other observations

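All tests in this part were chosen only after the result was seen, except that on the interferon list, whose bound was set before its adjusted median was known.

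Epithelial transcripts varied between libraries within every group. TP63, the transcription factor of basal stratified epithelium, ran from 0.18 to 23.2 CPM in control, 0.792 to 35.1 CPM in sham, 3.16 to 22 CPM in acellular and 0.59 to 16.5 CPM in PLATE. Genes of motile cilia were high in 3 libraries: FOXJ1, the master regulator of ciliogenesis, at 5.7, 2.61 and 2.81 CPM and HYDIN, a protein of the ciliary central pair, at 10.2, 15.9 and 9.37 CPM in control 16, control 24 and acellular 10, against at most 0.4 and 1.23 CPM in all others. The ciliated cell list, lower in sham than in control at a median log2 fold change of -1.98 (all 19 members lower, adjusted p = 0.00976, estimated-correlation adjusted p = 0.694), lost its call when any 1 of 3 libraries was left out. For ciliated cells the median was -0.56 without control 16 (adjusted p = 0.463), -0.705 without control 24 (adjusted p = 0.434) and -1.39 without sham 14 (adjusted p = 0.0716). Secretory genes ranged as widely: MMP7, an epithelial protease, from 11.1 to 9840 CPM, with all PLATE libraries at 1230 to 7930 CPM and all sham libraries at 443 CPM or less; CLU, the secreted chaperone clusterin, from 554 to 40600 CPM and OVGP1, the oviductal glycoprotein, from 8.73 to 932 CPM.

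Interferon-response genes followed the columnar epithelium across libraries. Over 16 libraries the means of the 2 lists had Pearson r = 0.906 (permutation p = 1e-05, the smallest possible, BH 4e-05) and Spearman rho = 0.847 (permutation p = 9e-05, BH 0.00036), r = 0.777 without control 2 and control 9, the libraries farthest from the median (permutation p = 0.00119), and r = 0.905 after group means were removed. The higher interferon list in acellular than in control libraries may thus come from more epithelium in the acellular samples: with the epithelium covariate its median went from 0.613 to 0.328, between the bounds set for and against this. The covariate fit gave adjusted p = 3.58e-07 with the preset correlation and 0.813 with an estimated correlation. The latter decides nothing, since it was 0.707 without the covariate, and the question stays open. Interferon response and MHC class II lists had r = 0.551 (permutation p = 0.029, BH 0.0387) and rho = 0.662 (permutation p = 0.00638, BH 0.0128), with r = 0.441 without control 2 and acellular 10, the libraries farthest from the median (permutation p = 0.117). Without control 2 and PLATE 1, r was 0.819 (permutation p = 0.00032), so that the strength of this relation depends on which libraries are left out.

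A hypothesis that samples differ in their mix of muscle wall and mucosa was tested on the smooth muscle and columnar epithelium lists. Pearson r was -0.627 (permutation p = 0.00698, BH 0.014) and Spearman rho -0.474 (permutation p = 0.0658, BH 0.0802), with r = -0.616 after group means were removed. Without control 2 and PLATE 1, r was -0.634 (permutation p = 0.0152), and without control 2 and control 9 it was -0.152 (permutation p = 0.604). Its size thus depends on which libraries are left out, and the hypothesis stays open. The bound against it was moved after this last r was seen. Smooth muscle and immediate early lists, the last of the 4 relations computed, had r = 0.413 (permutation p = 0.112, BH 0.112) and rho = 0.453 (permutation p = 0.0802, BH 0.0802), and r = 0.153 without control 2 and control 9. Immediate early genes varied within groups: FOS ran from 26.5 to 1880 CPM in control, 39.1 to 1170 CPM in acellular and 44.9 to 405 CPM in PLATE, and from 58.9 to 71.2 CPM in sham. Handling of the tissue before preservation could give such a spread, up to 6.15 log2 units within a group, but no label records it and no value decides. Of the 560 sets of 3 libraries, the sham set had the highest mean Spearman correlation, 0.983, against a median of 0.953. The set was singled out because it was seen to be alike, so this is a value and no test.

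For counts of genes the splits of the same libraries decide nothing about chance, because with a real count of 0 every split gives as many: 84 of 84 splits for sham against control (highest other 1), 84 of 84 for acellular against control (247), 100 of 100 for PLATE against control (415), 35 of 35 for PLATE against acellular (0) and for PLATE against sham (0), 100 of 100 for operated against control (465) and 100 of 100 for the joint test (1). The split with 247 genes set control 2, 16 and 25 apart, that with 415 control 2, 24 and 25 with PLATE 1, and that with 465 control 9 and acellular 10 with all PLATE libraries. Any call at all came from 8 of 84, 4 of 100 and 3 of 100 splits in these sets. Splits with so many genes point to a structure of the samples other than the groups, which was not tested. The counts at an unadjusted p under 0.05 were reached by 48 of 84 splits for sham against control and 37 of 84 for acellular against control. They were reached by 76 of 100 for PLATE against control, 24 of 35 for PLATE against acellular and 5 of 35 for PLATE against sham. For operated against control it was 69 of 100 and for the joint test 22 of 100, and for acellular against sham 2 of 10. For counts of lists, chance is not excluded: as many as the real 20 came from 7 of 84 splits for sham against control (highest other 23), as many as 14 from 43 of 84 for acellular against control (22), as many as 21 from 9 of 100 for PLATE against control (23), as many as 18 from 13 of 35 for PLATE against acellular (20) and from 11 of 35 for PLATE against sham (22), and as many as 16 from 58 of 100 for operated against control (22). For acellular against sham the 10 splits are too few to exclude chance; the real counts were 0 genes and 18 lists, and the highest others 0 and 18 (10 and 3 of 10 splits as many).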
